A study of Sus scrofa with 3 samples.

How the data were processed

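MicroRNA (miRNA) levels were measured in porcine alveolar macrophages, the resident phagocytes of the lung airspace, from 60-day-old animals. Per the labels' protocols, 2 to 5 µg of total RNA were extended with a poly(A) tail, an oligonucleotide tag was ligated to the tail, and the tag was stained with the red dye Cy5 for hybridization in 1 colour. There were 3 arrays: uninfected cells, cells 12 h after infection with porcine reproductive and respiratory syndrome virus (PRRSV) of strain HuN4, and cells 24 h after infection. Each group held 1 array, so the design has no replicates, no p-value was computed across samples, and the number of arrays limits the precision.

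Each array carried 3968 spots. There were 255 probes for pig miRNAs and 89 custom probes named after miRNAs of other species, each with 9 repeat spots. The remainder were 588 blank spots, 268 calibration spots and 16 spots for 5S ribosomal RNA. The deposited scanner files give the median fluorescence intensity of each spot and the SD of its pixels on a linear scale, per the file headers. No background had been removed from these intensities, as blank spots read a median of 102, 84.5 and 45.7 on the control, 12 h and 24 h arrays. The scanner and the image software are not given in the sources used here. The authors also deposited a table with 1 processed intensity per probe and array. Set against the background-subtracted scanner values of detected probes, its columns correlated on the log2 scale with r = 0.9993, 0.9995 and 0.9985, which shows a linear, uncentred scale in the same direction. How the authors normalized that table is not given in the sources used here. The medians of its columns were 47.8 for control, 47.8 for 12 h and 69.4 for 24 h, with 92, 59 and 57 values under 1. The table was used as an alternative. As it holds 1 value per probe, the spot SDs and detection calls for it were those of the scanner data.

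The files hold no local background and no background SD. The local background of a spot was therefore the median of its 20 nearest blank spots. Intensities were corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50) and put on the log2 scale. Quantile normalization between the 3 arrays was set on the spots of pig miRNAs, and the other spots were read off the same curves. The log2 values of the 9 repeat spots were then averaged. Normexp with this offset and quantile normalization both pull the log2 ratios of dim probes towards 0. Quantile normalization also gives the top ranks of the pig miRNA spots the same values on each array. This holds the ratios of the brightest miRNAs near 0. The detection rule fixed beforehand, a multiple of the background SD, could not be applied, and its stated fallback was used. A probe was detected when the median of its spots over local background was above the 95th percentile of the blank spots treated in the same way, which was 16.7, 9.43 and 5.12 intensity units on the control, 12 h and 24 h arrays. This threshold follows the background of each array and was lowest at 24 h.

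The comparisons were 12 h against control, 24 h against control and 24 h against 12 h. A miRNA counted as changed when it was detected on at least 1 of the 2 arrays, its log2 ratio was at least 1 in size, and this size exceeded the sum of the SDs between its repeat spots on the 2 arrays. Where only 1 of the 2 arrays detected it, the fold was given as a lower bound against the higher of its own signal and the lowest signal of a detected pig miRNA on the other array. In total 15 lists of miRNAs were fixed before the data were examined: families (let-7, miR-17-92, miR-30, miR-29, miR-23/27/24, miR-99, miR-100 and miR-125 as 1 family and miR-15/16), miRNAs induced in inflammation, miRNAs enriched in myeloid cells, miRNAs reported in work on PRRSV, and markers of epithelial, erythroid, endothelial, lymphoid and mesenchymal or muscle cells. The median log2 ratio of a list's detected members was placed among 10000 random lists of the same size, matched on mean signal. This is a description of these arrays, not a test. The correlation of the 12 h and 24 h ratios was set beside 1000 simulations of unchanged arrays with the noise of the repeat spots and a shared control array.

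Named miRNAs followed a rule fixed beforehand. In each comparison it took the up to 10 largest increases and 10 largest decreases among changed miRNAs detected on both arrays, up to 5 detected on 1 array only in each direction, up to 4 changed members of each list or otherwise its 2 brightest, and the 5 miRNAs of highest control signal. Other named probes were chosen after their values were seen and are marked so. Names are those of the array. Of the 188 detected pig miRNAs, 170 were matched by name to the RefSeq annotation of Sscrofa11.1, which served for neighbouring genes only. Positions are not printed because the build behind the array design is not given in the sources used here.

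The procedure was tested on simulated data made from the mean signals of the 3 arrays over 255 probes for the comparison of 12 h against control. Among 20 miRNAs simulated with a 2-fold change, 5 were called, and among 20 with a 4-fold change, 16 were called. These were drawn from miRNAs detected on all 3 arrays, so the rates do not cover probes that an array failed to detect. No call fell among 215 unchanged miRNAs. The simulated noise was that of repeat spots and blank spots only, so this count does not cover differences between arrays. The median log2 ratio recovered was 0.82 in size for a 2-fold change and 1.45 for a 4-fold change. The alternatives covered the background correction, the normalization, the summary and choice of repeat spots, the filter on dim probes and the authors' table. A single background per array and a 99th percentile for detection were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the comparisons.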

Results

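The series profiled miRNAs early in the infection of porcine alveolar macrophages by PRRSV, an arterivirus that replicates in these cells. Uninfected control cells and cells at 12 h and 24 h after infection with strain HuN4, a highly pathogenic isolate, were each measured on 1 array. There are no biological replicates. Each ± below is an SD between the 9 repeat spots of a probe, combined over the 2 arrays for a log2 ratio, and covers technical error within arrays only.

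The control array detected 137 of the 255 pig miRNAs, the 12 h array 152 and the 24 h array 188. All 3 arrays detected 136, 16 were detected on both infected arrays and not on the control array, 35 on the 24 h array only, and 67 on none. The median spot SD of detected miRNAs was 0.12, 0.10 and 0.09 on the log2 scale for control, 12 h and 24 h. Detection widened as the blank spots dimmed, from a median of 102 on the control array to 84.5 at 12 h and 45.7 at 24 h, and with the 99th percentile of blank spots as the threshold the counts were 134, 144 and 126. Among the pig miRNAs, the most intense control signals were those of miR-21, a miRNA abundant in activated myeloid cells, and of the miR-23/27/24 clusters. Over local background, miR-21 read 20998 ± 2374 intensity units on the control array, 21139 ± 1648 at 12 h and 26706 ± 1245 at 24 h, and miR-23a read 16851 ± 1412, 17247 ± 1352 and 14995 ± 1273.

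At 12 h, the comparison with control asked which miRNAs differ early after infection. Of 153 detected miRNAs, 2 changed: miR-4334-5p rose and miR-1306-3p fell. miR-4334-5p, a miRNA described in the pig that lies within the aminopeptidase gene DNPEP, was 4.36-fold higher, with a log2 ratio of 2.12 ± 0.10 and background-subtracted signals of 477 ± 36.9 on control and 2808 ± 91.6 at 12 h. miR-1306-3p, encoded within DGCR8, the gene of a subunit of the Microprocessor that releases miRNA precursors, was 2.52-fold lower (log2 ratio -1.34 ± 0.17), with signals of 793 ± 69.5 and 292 ± 30.4. A further 147 miRNAs (96.1%) differed by less than 1.5-fold. The 5 brightest pig miRNAs (miR-21, miR-23a, miR-27a, miR-24 and miR-23b) had log2 ratios from -0.11 for miR-24 to 0.14 ± 0.13 for miR-23b. The normalization gives the top ranks of each array the same values, so these ratios do not show that the brightest miRNAs were unchanged.

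By list, let-7 stood apart at 12 h. All 7 members of this family of differentiation-associated miRNAs had a log2 ratio above 0, with a median of 0.30 that exceeded 99.8% of random lists, although no member passed the rule for change. The 7 probes each lie within 2 mismatches of another, so they are not independent as random lists are. Without let-7e (0.67 ± 0.25) and miR-98 (0.46 ± 0.14), which lie near the brighter let-7a, the median was 0.28. Among the others, let-7g gave 0.15 ± 0.18 and let-7i 0.08 ± 0.15. No other list left the central 95% of random lists, and none had a changed member. The median was 0.10 for the 4 detected inflammation-induced miRNAs, among them miR-146b at 0.16 ± 0.13, an inhibitor of signalling downstream of Toll-like receptors. The pig probes named miR-155 and miR-146a in this list do not carry the guide strands of these miRNAs and were not detected at 12 h or on the control array. The list median was -0.03 for the 14 myeloid miRNAs and 0.01 for the 20 miRNAs from work on PRRSV. It was -0.19 for the 9 detected members of the proliferation-linked miR-17-92 family, with 2 above 0, and 0.27 for the 5 of the miR-99, miR-100 and miR-125 family. The miR-30 family lay at 0.05, the miR-29 family at -0.09, the miR-23/27/24 clusters at -0.02 and the miR-15/16 family at 0.03. Markers of other cell types had medians of -0.22 for epithelium (1 detected, miR-205), -0.06 for erythroid cells (2), -0.08 for endothelium (1, miR-126), 0.20 for lymphocytes (4) and 0.21 for mesenchymal or muscle cells (5). Some of these members were not detected on the control array, so their ratios are set against background and carry little weight. They are miR-486 of the erythroid list (signals of 3.95 ± 12.3 on control and 14 ± 7.25 at 12 h), miR-126 (9.74 ± 8.40 and 10.8 ± 7.21), 2 lymphocyte members and 1 mesenchymal or muscle member. Members detected on both arrays had medians of -0.17 (miR-451), 0.02 (2 lymphocyte members) and 0.08 (4 mesenchymal or muscle members). The muscle miRNA miR-133a-3p in the last list read 0.86 ± 0.13, under the 2-fold limit.

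With no normalization between arrays the 12 h count was 3 (2 higher and 1 lower), and with the authors' processed values it was 10 (8 higher and 2 lower). Detected probes with at least 50% G in their sequence, miR-4334-5p left out, had a median log2 ratio of 0.21 at 12 h. Of these 13 probes, 12 were custom probes.

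At 24 h, 9 of 188 detected miRNAs changed against control, 8 higher and 1 lower. miR-4334-5p rose 6.72-fold (log2 ratio 2.75 ± 0.16) to a signal of 4224 ± 329, and miR-1306-3p was again lower, by 3.03-fold (log2 ratio -1.60 ± 0.18, signal 281 ± 26.6). The other arms of these precursors were looked at after the values were seen. miR-1306-5p moved less, at -0.29 ± 0.12. Between 12 h and 24 h, miR-4334-3p read -0.20 ± 0.14 and miR-4334-5p 0.63 ± 0.13. As miR-4334-5p already read 2.12 over control at 12 h, this interval does not show whether miR-4334-3p followed that earlier rise. The other changed miRNAs rose by between 2.05-fold and 2.54-fold at 24 h against control where both arrays detected them. miR-497 of the miR-15/16 family, whose members restrain cyclins, rose with a log2 ratio of 1.35 ± 0.19, from a signal of 167 ± 25 to 720 ± 62.8. let-7e rose by 1.33 ± 0.33, miR-129b by 1.27 ± 0.17, miR-29b, a miRNA that targets collagen and DNA methyltransferase transcripts, by 1.15 ± 0.11, miR-361-5p by 1.11 ± 0.18 and miR-374a by 1.03 ± 0.20 on the log2 scale. miR-615, encoded within HOXC5, was not detected on the control array (8.55 ± 6.07) and read 270 ± 40.1 at 24 h, at least 3.00-fold higher.

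**Figure D1:**
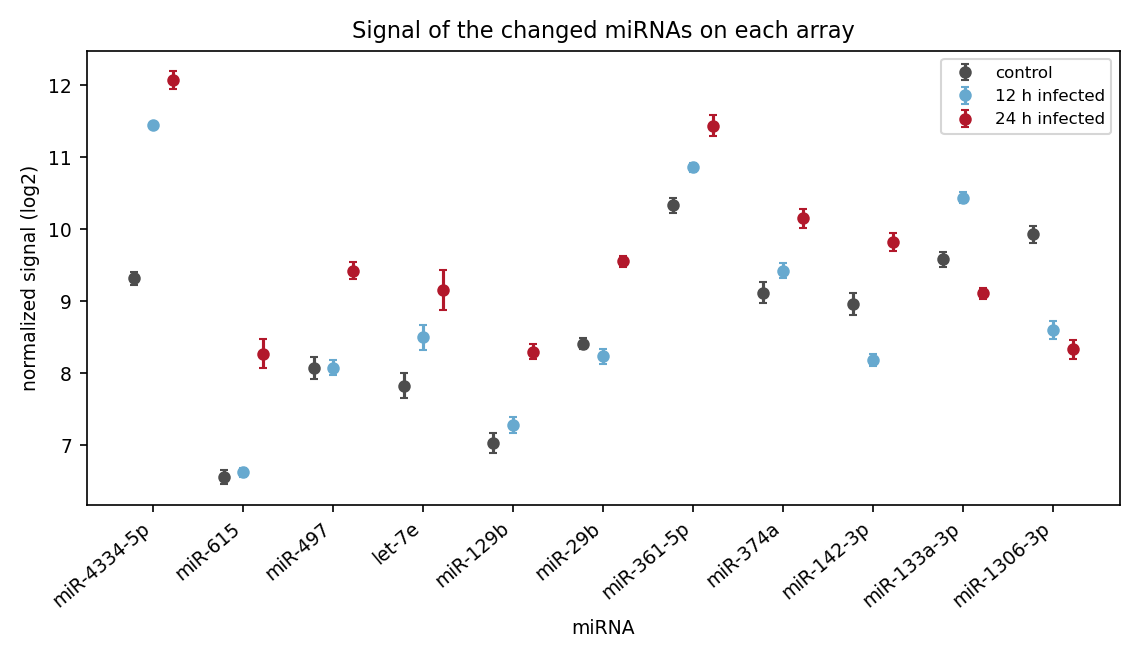
Normalized log2 signal of the 11 miRNAs that changed in 1 or more of the 3 comparisons, on the control (grey), 12 h (blue) and 24 h (red) arrays, in order of their 24 h log2 ratio. Points are means and bars SDs over 9 repeat spots of 1 array. miR-4334-5p is higher and miR-1306-3p lower on both infected arrays, while miR-497, miR-29b and miR-615 (not detected on the control array) stand apart at 24 h.

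Within 3 families a single member rose at 24 h. Of 7 let-7 members, let-7e rose and 6 did not change, with 3 above 0 and a list median of -0.005. All 3 miR-29 members lay above 0, with miR-29a at 0.51 ± 0.10 and miR-29c at 0.27 ± 0.10, and miR-29b alone passed the rule for change. The miR-29 median of 0.51 was higher than 96.8% of random lists, and it left the central 95% in 7 of 14 alternatives. Of 8 members of the miR-15/16 family, miR-497 rose and 7 did not change (median 0.03). The inflammation-induced list again held no changed member (6 detected, median -0.02), with miR-21 at 0.04 ± 0.22 and miR-146b at 0.05 ± 0.63, where 1 of 9 spots at 24 h read 2219 and the others between 7878 and 8463, which gave 0.25 ± 0.12 without that spot. The normalization holds the ratio of miR-21, the brightest pig miRNA on each array, near 0. Its signals over local background were 20998 ± 2374 on control and 26706 ± 1245 at 24 h. The myeloid list (15 detected, median 0.02) and the PRRSV list (21 detected, median -0.10, and -0.24 over the 17 detected on both arrays) held none either. The brightest members of the latter, miR-23a and miR-23b, read -0.05 ± 0.20 and -0.06 ± 0.15. Of the 21, 6 lay above 0, among them miR-30c at 0.22 ± 0.13. Also in this list, miR-181a and miR-125b were picked out after the values were seen. miR-181a, reported to target the PRRSV genome and its receptor CD163, read -0.38 ± 0.10. miR-125b, reported to act on the NF-κB pathway in this infection, read -0.44 ± 0.12. Both falls rest largely on the normalization. Signals over local background were 199 on control and 187 at 24 h for miR-181a, and 952 and 921 for miR-125b. The medians were 0.14 for miR-30, -0.05 for miR-17-92, -0.03 for miR-23/27/24 and -0.08 for miR-99, miR-100 and miR-125.

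The erythroid list alone was outside the central 95% of random lists at 24 h, a result that depends on a probe at background. Its 2 members had a median of -0.51, lower than all but 0.12% of random lists, and neither passed the rule for change. miR-451, the dominant miRNA of red cells, read -0.78 ± 0.12. miR-486 (-0.23 ± 0.20) was not detected on the control array, and its signals went the other way, from 3.95 ± 12.3 to 5.15 ± 2.54. With detection on both arrays miR-451 was left alone, at percentile 3.83, inside the range. The list was also inside it with the 99th percentile for detection, where the PRRSV list was outside, and with a single background per array, where miR-29 was outside. Markers of the other cell types were at -0.45 for epithelium (miR-205, -0.45 ± 0.11), -0.01 for endothelium (miR-126, not detected on control and 22.7 ± 5.65 at 24 h), -0.04 for lymphocytes (5 detected) and 0.00 for mesenchymal or muscle cells (7 detected). The last 2 lists each hold 3 members not detected on control, and without these their medians were -0.31 and -0.18.

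The 24 h count was 50 (43 higher and 7 lower) with the authors' processed values, and all 9 miRNAs were among them. That count took its spot SDs and detection calls from the scanner data as processed here. On the 24 h array, calibration probes whose names end in 3M05 or 3M10 also read higher, with median log2 ratios of 1.56 and 0.68 against -0.08 for those ending in 3P, and the probes of let-7e and miR-29b each lie within 1 mismatch of a brighter probe (let-7a and miR-29c). The G-rich probes other than miR-4334-5p had a median of 0.58 over 14 probes, 12 of them custom probes.

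**Figure D2:**
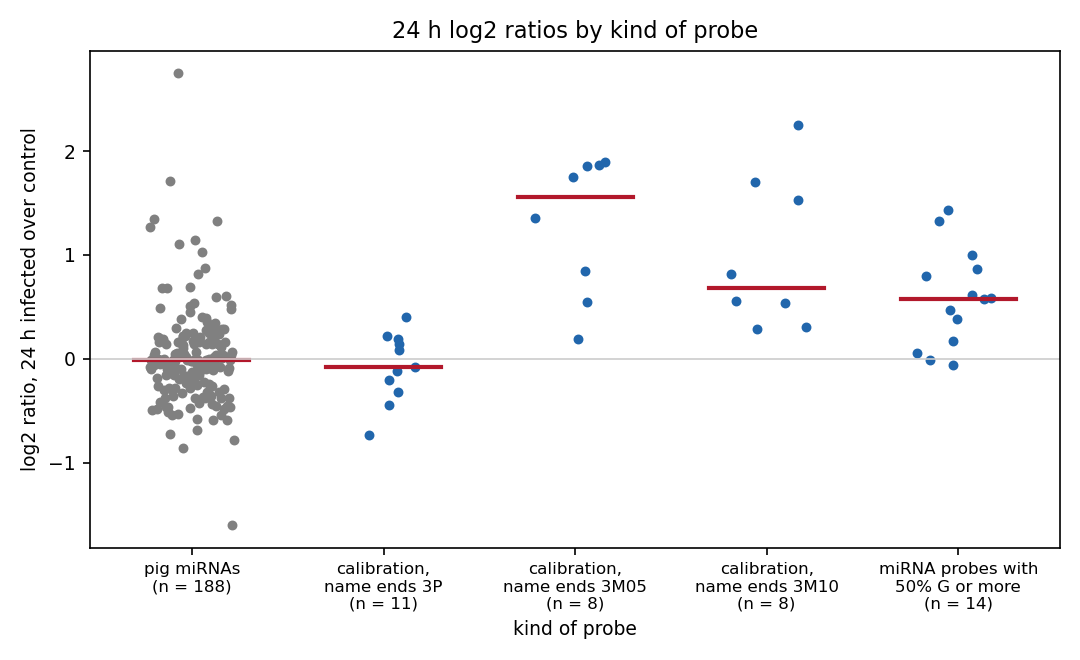
Log2 ratio of 24 h over control for each kind of probe: pig miRNAs detected on either array (188), calibration probes by the ending of their names (11, 8 and 8 detected), and the 14 other detected miRNA probes with at least 50% G. Each point is a probe and red lines are medians, which lie at -0.02 for pig miRNAs, -0.08 for 3P, 1.56 for 3M05, 0.68 for 3M10 and 0.58 for the G-rich probes.

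Between 12 h and 24 h, 6 of 188 detected miRNAs changed, 5 higher and 1 lower at 24 h. miR-615 rose by 1.65 ± 0.21 on the log2 scale and miR-142-3p, a miRNA largely restricted to blood cells, by 1.64 ± 0.15, from a signal of 199 ± 18.1 at 12 h to 977 ± 81.0 at 24 h, with 374 ± 34.5 on the control array. miR-497 (1.35 ± 0.16), miR-29b (1.32 ± 0.13) and miR-129b (1.01 ± 0.15) rose over the same interval. miR-133a-3p fell 2.52-fold, from 1352 ± 101 at 12 h to 560 ± 44.0 at 24 h, with 609 ± 57.3 on the control array.

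Of the lists, the myeloid list held 1 changed member of 15 (miR-142-3p, list median 0.00), and the miR-29 (3 members, median 0.46) and miR-15/16 (8 members, median -0.004) lists held 1 each. The mesenchymal and muscle list held the fall of miR-133a-3p (7 detected, median 0.11, and -0.12 without 2 members not detected at 12 h). The erythroid list was again outside the central 95% (median -0.45, lower than all but 0.09% of random lists), with signals of miR-486 close to background. It was inside in 3 of 14 alternatives: the 99th percentile for detection, a single background per array and plain subtraction. The PRRSV list (21 detected, median -0.20, percentile 2.60) was within the range and outside it with plain subtraction. The let-7 list (median -0.33, percentile 3.89) was within it and outside in 4 of 14 alternatives. The medians of the remaining lists lay between -0.25 (miR-99, miR-100 and miR-125) and 0.07 (endothelium), with the inflammation-induced list at -0.04, or -0.25 over 4 members detected on both arrays. The count was 37 (32 higher and 5 lower) with the authors' processed values.

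The changes at the 2 times were compared across the 188 miRNAs detected on any array, which are not independent replicates. Both miRNAs that changed at 12 h, miR-4334-5p and miR-1306-3p, also changed at 24 h in the same direction. Independent lists of 2 and 9 would share 0.096, a value that leaves out the shared control array, and unchanged arrays with the noise of repeat spots shared 0 in each of 1000 simulations. Neither value covers an odd reading of a probe on the control array, which would place it on both lists. The log2 ratios correlated with Pearson's r = 0.55 and Spearman's rho = 0.42, and 122 (64.9%) had the same sign. Unchanged arrays that share 1 control array gave r = 0.50 and the same sign in 70.0% (95% of simulations between 63.3% and 76.1%), so the share of equal signs showed no excess. The covariance was 0.0751 against 0.00197 in the simulation, a difference of 0.0731. The simulated noise covers repeat spots only, and part of the excess may come from the shared control array, which cannot be split. Without miR-4334-5p and miR-1306-3p, r was 0.35.

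**Figure D3:**
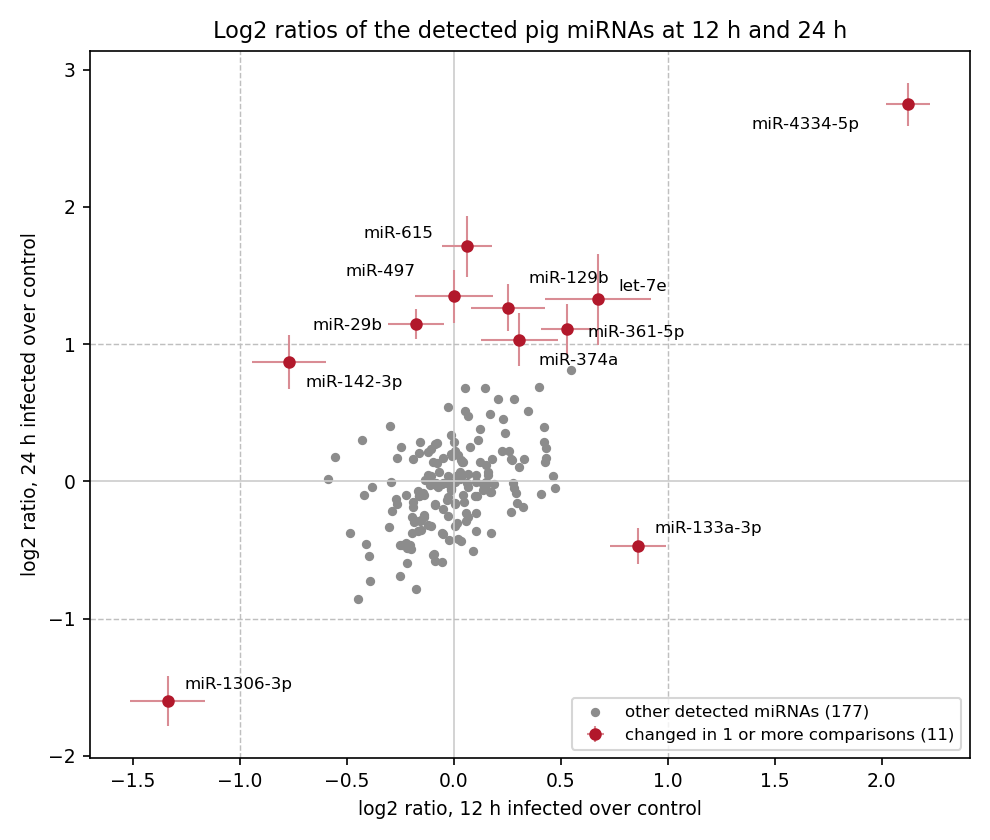
Log2 ratio at 24 h over control (vertical axis) against log2 ratio at 12 h over control (horizontal axis) for 188 pig miRNAs detected on at least 1 array. Red points are the 11 miRNAs that changed in 1 or more comparisons, with SDs between repeat spots, grey points the other 177, and dashed lines mark a log2 ratio of 1 in either direction. miR-4334-5p and miR-1306-3p lie beyond the lines at both times, and miR-133a-3p and miR-142-3p lie on opposite sides of 0 at the 2 times.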

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

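The tests in this part were chosen after the results they bear on were seen. On the normalized scale, miR-133a-3p and miR-142-3p moved in opposite directions at the 2 times, each by more than the summed spot SDs. For miR-133a-3p the fall below control at 24 h rests largely on the normalization. Its signals over local background were 609 ± 57.3 on control and 560 ± 44.0 at 24 h. Those of a second probe of the same sequence were 565 ± 73.0 and 562 ± 56.0. The log2 ratio against control of miR-133a-3p was 0.86 at 12 h and -0.47 at 24 h, and that of miR-142-3p was -0.77 at 12 h and 0.87 at 24 h. Whether the effect differs between the times was not tested, as each time has 1 array. The other arm of the same precursor, miR-142-5p, read -0.59 ± 0.12 at 12 h and 0.02 ± 0.16 at 24 h, and a second probe with the sequence of miR-133a-3p read 0.95 ± 0.16 and -0.38 ± 0.18. Among miRNAs that rose at 24 h against control, the other arms of miR-361-5p and miR-374a did not follow. There miR-361-3p read -0.26 ± 0.19 and miR-374a* read 0.17 ± 0.29.

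The calibration spots lie outside the comparisons of the report, and some carried a signal at 24 h above that of the control array. At 24 h, 9 of 43 calibration probes met the rule for change, all higher, with the highest log2 ratio at 2.25 for the probe named Ctr09-3M10, and none met it at 12 h. Of the 43 probes, 33 come as sets with a shared number and the endings 3P, 3M05 and 3M10, and these held 8 of the 9. The 3P probes had a median of -0.08 at 24 h, and none of them met the rule. In 10 pairs detected on all arrays, the signal of the 3M probe was a median of 1.68% of its 3P partner on the control array, 1.89% at 12 h and 8.92% at 24 h, and all 10 pairs were higher at 24 h than on control. What the endings stand for is not given in the sources used here.

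The rise of 8 miRNAs at 24 h has technical and biological readings. A rise of the shared primary transcript is argued against for let-7e, as far as mature levels on 1 array show. Its partners within 10 kb, miR-125a and miR-99b, read -0.09 ± 0.13 and 0.16 ± 0.18 at 24 h. For miR-497 such a rise stays open. Its partner miR-195 read -0.04 ± 0.16, but that probe lies within 2 mismatches of the brighter bta-miR-16 (control signals of 167 and 4772). The median over these partners of let-7e and miR-497 was -0.043. A shared rise also stays open for miR-29b, whose partners miR-29a (0.51 ± 0.10) and miR-29c (0.27 ± 0.10) had a median of 0.39. Lower hybridization specificity on the 24 h array is a candidate explanation: of 13 detected miRNA probes within 3 mismatches of a probe at least 4 times brighter, 5 were not detected on control and were left out. Without let-7e and miR-29b, the other 6 had a median of 0.22, just above the 95% range of random sets matched on signal (-0.38 to 0.20), with 4 above 0. The margin is narrow and the probes are few. This explanation covers let-7e and miR-29b directly, 2 of the 8 (p = 0.0977 for the share of near matches among the 8 in Fisher's exact test, two-sided). That test ran over all 188 detected miRNAs and all 13 near matches, including those not detected on control. The other risen miRNAs, miR-497, miR-615, miR-129b, miR-361-5p, miR-374a and miR-4334-5p, have no such brighter probe on the array. An effect of infection cannot be told apart from a property of the array, since infected arrays at 24 h number 1.

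The rise of miR-4334-5p on both infected arrays was weighed against a shift of probes for G-rich sequences, as its sequence CCCUGGAGUGACGGGGGUG holds 52.6% G. The other 13 detected probes with at least 50% G, 12 of them custom probes, had a median 12 h log2 ratio of 0.21, above 99.8% of random sets matched on signal, with 12 above 0, and a median of 0.58 over 14 probes at 24 h. Some are near copies of each other (miR-198 and miR-483 of different species), so they are not independent. The 1 pig probe among the 13, miR-885-3p, read -0.26 ± 0.25 at 12 h, so the 12 h shift was seen in custom probes only. At 24 h the 2 pig probes, miR-885-3p and miR-92b-5p, read 0.17 ± 0.19 and -0.06 ± 0.17. By G and C together, the 31 detected pig probes with at least 60% had a 12 h median of -0.15, against 0.01 for the other 122. A shift of G-rich probes stays a candidate explanation for part of the rise, although the pig probes did not show it at 12 h. The highest of the others, miR-638 at 1.02 ± 0.13, also lay well under 2.12 at 12 h. Within that part, an effect of infection cannot be told apart from such a shift. For the rest, it cannot be told apart from another property of the array, since infected arrays at 12 h number 1.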

How the results depend on the processing

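No paired analysis was possible because each group holds 1 array, and for the same reason no replicate could be left out. In each of the 14 alternatives the 17 named ratios of changed miRNAs kept their direction (238 of 238 values), and 14 also stayed changed in all. miR-374a at 24 h lost its call with odd repeat spots (0.97) and the median of repeat spots, miR-129b at 24 h against 12 h with odd repeat spots (0.96), and miR-615 at 24 h with detection on both arrays. The counts of changed miRNAs stayed within 1.5 times under every alternative but the authors' processed values (10, 50 and 37 for 12 h against control, 24 h against control and 24 h against 12 h, with a correlation of 0.80 between the times). All changed miRNAs were among those called there, and 57 to 92 values per array of that table lie under 1, but the cause was not tested. The spot SDs and detection calls set against that table came from the scanner data as processed here. The number of lists outside the central 95% of random lists, 1 in each comparison, was less stable. At 12 h it was 2 with no background correction, cyclic loess, the median of repeat spots, the authors' values or detection on both arrays, and 3 with plain subtraction, no normalization or 75th percentile scaling. At 24 h against control it was 2 with no normalization, 75th percentile scaling, cyclic loess, odd repeat spots, the authors' values or no filter, and 0 with detection on both arrays, where 1 erythroid member was left. At 24 h against 12 h it was 2 with no background correction, offset 16 or the authors' values, and 0 with the 99th percentile for detection (chosen after seeing the data). The let-7 median at 12 h stayed outside in 14 of 14 alternatives (0.28 to 0.42), and the erythroid medians in 11 of 14. With the 99th percentile the PRRSV list, and with a single background per array the miR-29 list, took the place of the erythroid list at 24 h, so the count stayed 1. Of the 1786 alternative values of named miRNAs and list medians, 219 moved by more than the spot SD. Scaling to the 75th percentile shifted the median ratio of all miRNAs to -0.11 at 12 h and -0.10 at 24 h, without turning the sign of a list outside the range. Not run were the mean foreground, which the files do not give, and detection at 5 times the background SD, which they do not give either. Signal over background limits the dim probes: at 24 h miR-615 ranged from 1.62 to 4.32 and miR-129b from 1.18 to 2.24 over the alternatives.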

Other observations

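The custom probes, named after miRNAs of other species and described here after their values were seen, show changes outside the pig set. Of 71 detected at 24 h, 4 rose and 1 fell against control. The fall was that of mmu-miR-34b-3p, an arm of a p53-responsive miRNA also abundant in ciliated epithelium, from 1511 ± 89.2 on control to 1169 ± 79.3 at 12 h and 391 ± 24.4 at 24 h (log2 ratio -1.96 ± 0.10 at 24 h). Other probes named after this family gave no such signal. Neither rno-miR-34b nor the pig probe of miR-34c was detected on any array, and bta-miR-34b was detected at 24 h only. As none of these is named for the same arm, they do not check the fall, which rests on 1 probe. The rises were those of miR-638 (1.32 ± 0.16) and miR-663 (1.43 ± 0.24), both with at least 50% G, of mmu-miR-678 (1.45 ± 0.20), and of miR-23b*, which was not detected on the control array and was at least 2.38-fold higher at 24 h. At 12 h, miR-638 alone changed, from 3685 ± 299 to 8296 ± 414.

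The probe mmu-miR-155 carries UUAAUGCUAAUUGUGAUAGGGGU, the guide strand of a miRNA induced in macrophage activation. It read 299 ± 26.3 on control, 570 ± 58.0 at 12 h and 577 ± 64.4 at 24 h, with log2 ratios of 0.73 ± 0.18 and 0.51 ± 0.17, beyond the spot SDs at both times and under the 2-fold limit. The pig probe named miR-155 carries another sequence, UCCUACAUGUUAGCAUUAACA, and was detected at 24 h only, at 6.0 ± 2.67. The pig probe named miR-146a carries CCUGUGAAGUUUAGUUCUUCAG, which is not the guide strand either, and was detected on no array. The inflammation-induced list of the report holds these pig probes, so it does not measure the guide strands of miR-155 and miR-146a.

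The array held 10 pairs of probes with identical sequence, of which 8 gave log2 ratios that could be compared. Over these, the 22 log2 ratios differed by a median of 0.07 and by at most 0.39.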
